A study of Mus musculus with 2 samples.

How the data were processed

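Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on mouse Th2 cells, the helper T cells that secrete interleukin 4. Per the labels' protocols, T cells positive for CD4 and CD62L from the spleen of C57BL/6 mice were activated through CD3 and CD28 for 5 days with IL-4 at 10 ng/ml and an antibody against interferon gamma at 2 µg/ml. The cells were then rested for 3 days. They were crosslinked in 0.4% formaldehyde, and the chromatin was sonicated and precipitated with 7 µg of antibody. Fragments of about 200 bp were taken from a gel for single-end Illumina sequencing, and the PCR preceded the gel step. One library was made with an antibody against acetylated lysines of histone H3 (H3KAc), a mark of active chromatin. The other was made with non-specific rabbit IgG, which measures the background.

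The deposited files hold 1 row per aligned read, with its chromosome, position and strand. All intervals were 35 bases long, and the remaining columns held 0 in every row. Per the submitters' processing notes, reads were aligned with Bowtie to mm9. The Bowtie version, the treatment of reads with several alignments and any quality filter are not given in the sources used here. The files give positions of single reads without normalization, so every count below was computed from them. The gene table used here is on another build (GRCm38), so no coordinate was taken from it and no gene is named. Promoter levels, profiles around transcription start sites, gene lists and gene loci, which had been planned, were not analysed here.

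Reads with the same chromosome, 5' end and strand were counted 1 time, because copies made by PCR carried no molecular identifier. Each read was moved 100 bp along its strand, 0.5 of the fragment length in the protocol, and assigned to 1-kb bins. Levels are reads per 1000000 distinct positions (RPM), or per 1000000 reads where all deposited reads were counted. The H3KAc over IgG ratio of RPM was given its exact conditional binomial (Clopper-Pearson) 95% interval. A bin with at least 5 reads in both libraries together was called enriched when the lower bound was above 2, and under-represented when the upper bound was below 0.5. Enriched bins with at most 1 bin between them were joined into regions. Levels of single regions have exact Poisson 95% intervals. All intervals and bounds cover counting error only. A ratio against 0 IgG reads has no upper bound, and the lower bound of its 95% interval is given as the least fold. Coordinates are 1-based.

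There was 1 library per group. No p-value was therefore computed, the differences have no replicate check, and every interval compares these 2 libraries, not the conditions. The bin width, the calling rule, the regions to be named and the first set of alternative settings were fixed before the data were examined. The named regions are the 20 with the highest lower bound, the 10 widest (ties by lower bound) and the 5 bins with the most IgG reads. These settings were all reads as deposited, reads not moved, IgG scaled by background bins of 10 kb, lower bounds above 4 and above 1, H3KAc reads thinned to the IgG number, 500-bp bins and regions not joined. Alternatives chosen after seeing the data were IgG reads summed over the 11 bins centred on each bin, read shifts measured in each library, and reads of the plus or the minus strand alone. A comparison by H3KAc level, in which the level classes came from a random part of the H3KAc reads and the values from the rest, was also added then.

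The calling was tested on simulated data of 2246042 bins with the real depths. Both libraries shared 1 rate per bin, taken from their summed real counts, apart from the raised bins. Counts were drawn independently from Poisson distributions. The raised bins were drawn from those with at least 5 real reads in both libraries together, so the shares called do not cover bins with fewer. Of 200 bins raised 4-fold in H3KAc, 1.5% were called, against 28.0% of those raised 8-fold, 79.0% of those raised 16-fold and 99.5% of those raised 32-fold. Among 2245242 bins simulated without a difference, 1 was called enriched and 838 under-represented. Real IgG read starts were often paired on opposite strands (given below), so their counts may vary more and these numbers may not carry over. With IgG over 11 bins, 59.0% of the 4-fold bins were called, but so were 18800 bins simulated without a difference, because that rule also calls places where both libraries peak. Most of the summed reads came from H3KAc, so its peaks were built into both simulated libraries. The 18800 bins are therefore no estimate of false calls in the real data. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.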

Results

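The study title names a method for measuring the level of a histone modification at each gene, and the series holds an H3KAc library and an IgG control library from the same kind of cell. The question addressed here is where, and by how much, acetylated histone H3 lay above the non-specific background. The H3KAc library held 21845451 aligned reads at 19711169 distinct positions. The IgG library held 7626703 reads at 1897666 distinct positions. A distinct position was read 1.11 times on average in H3KAc and 4.02 times in IgG, and 91.6% and 26.4% of positions, respectively, were read 1 time. Of 2246042 covered 1-kb bins, 60.5% had no IgG read and 0.922% no H3KAc read. The mean was 8.78 H3KAc and 0.845 IgG reads per bin, so the depth of IgG limited the precision of every ratio.

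The spacing of reads on opposite strands differed between the libraries. Averaged over 25 bp, the distance from a plus-strand read start to minus-strand starts peaked at 57 bp in H3KAc and at 157 bp in IgG, against about 200 bp for the gel-purified DNA in the protocol. At these averaged peaks, pairs were 2.98 times as frequent as at distances beyond 800 bp in H3KAc and 4.67 times in IgG.

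**Figure D1:**
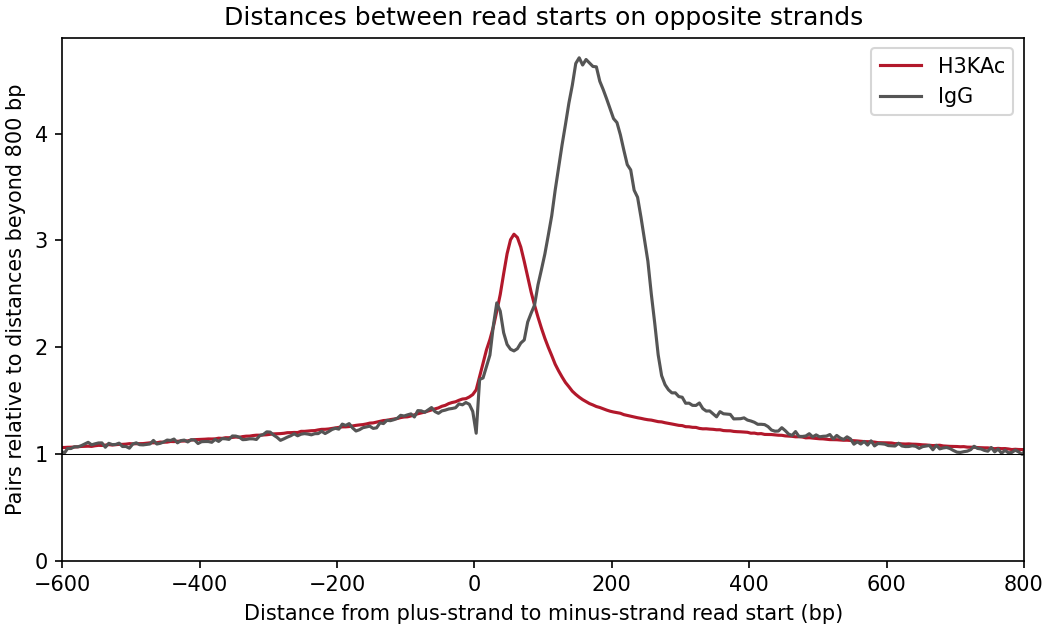
Number of pairs of distinct read starts on opposite strands (y axis, relative to distances beyond 800 bp) by distance in bp (x axis), for the H3KAc and the IgG library. The curves are drawn in steps of 5 bp without averaging, and the highest step begins at 55 bp in H3KAc, at 3.06, and at 150 bp in IgG, at 4.71.

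H3KAc stood above IgG in the bins at the top of the H3KAc range, and pooled ratios in the lower classes lay between 0.882 and 1.09. Each library was scaled to its own total and most reads lay below the top 1% of bins, which holds the pooled ratio there near 1. Single bins in the lower classes may still differ between the libraries. Bins were ranked by a random part of the H3KAc reads and measured with the rest, so that neither the measured H3KAc reads nor the IgG reads entered the ranking. Both parts came from the same library, so a trait particular to that library enters both. In the top 1% of bins (21057 bins), H3KAc was 4.12 RPM per kb and IgG 2.17 RPM per kb, a ratio of 1.89 (95% interval 1.88 to 1.91). These bins held 8.67% of H3KAc reads and 4.58% of IgG reads. The ratio was 0.882 (0.879 to 0.885) in bins between the 90th and 99th percentile and 0.920 (0.918 to 0.922) between the 50th and 90th. It was 1.09 (1.090 to 1.097) in the lower 50%. Bins with tied counts fell in the same class, so this class held 1274920 of the 2246042 bins. The classes from the 50th and from the 90th percentile held 787710 and 162355. IgG rose with the H3KAc level, from 0.199 RPM per kb in the lower 50% to 1.38 RPM per kb between the 90th and 99th percentile. In the top 0.1% (2201 bins) the ratio was 1.57 (1.55 to 1.59), and 2.09 (2.06 to 2.13) without bins in which H3KAc averaged more than 2 reads per position. That filter used all H3KAc reads, including the measured ones.

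**Figure D2:**
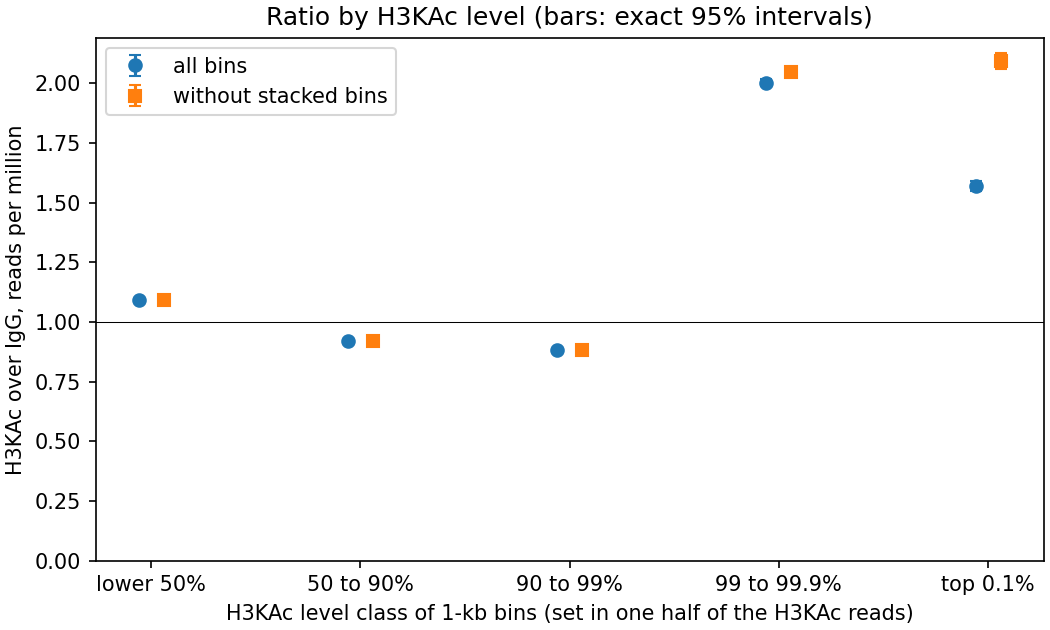
Ratio of H3KAc to IgG in RPM (y axis) for 1-kb bins grouped by H3KAc level (x axis), with exact 95% intervals, for all bins and without bins averaging more than 2 H3KAc reads per position. The ratio lies between 0.882 and 1.09 up to the 99th percentile and reaches 2.00 in the class just below the top 0.1%.

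Regions in which the lower bound of the ratio exceeded 2 lay on all autosomes. By this rule, fixed in advance, 1178 bins were enriched, and they formed 1117 regions, of which 1059 (94.8%) were 1 kb wide, 51 were 2 kb and 7 were 3 kb or wider. With a lower bound above 1, 9177 bins formed 7135 regions, of which 1613 were wider than 1 bin. The 1178 bins held 0.764% of H3KAc reads and 0.0383% of IgG reads, with a median of 121 H3KAc reads per bin. Of the regions, 4.66% lay within 10 kb of another, against 1.28% on average and at most 2.51% in 100 random placements on covered bins of the same chromosomes. The placements were not matched in depth to the called bins, each of which held at least 79 H3KAc reads. An uneven spread of deep bins was therefore not separated from this excess. H3KAc stayed above its surroundings beyond the called bins, at 1.57 RPM per kb between 1 and 2 kb from region centres and 0.903 RPM per kb beyond 4 kb. No IgG read was found in 59.0% of called bins, against 60.5% of all covered bins. Covered bins had a median of 6 H3KAc reads, so the called bins and all covered bins are not alike in level. The rule favours bins with few IgG reads. IgG was 0.334 RPM per kb within 500 bp of region centres, 0.765 between 1 and 2 kb and 0.711 beyond 4 kb. In between it was highest, at 1.16 and 1.15 RPM per kb 550 bp to either side and 1.25 at 650 bp on the right. This step lies at the edge of the 1-kb regions, which the rule selected for few IgG reads. The low centre is therefore not read as a depletion of IgG. When both libraries were divided at random, bins called in the first part had a ratio of 69.5 there and of 5.80 in the second part. Of the 128 bins called in the first part, 19 (14.8%) were also called in the second. The ratios of single regions given below carry the same upward bias, and so do their lower bounds, including those written as "at least". These bounds cover counting error and not the choice of regions from all bins.

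The region with the highest lower bound lay on chromosome 6 from 119429001 to 119431000 (mm9). It had 24.5 RPM in H3KAc (95% interval 22.4 to 26.8) from 483 reads and 1 IgG read, a ratio of 46.5 (8.31 to 1840). The next lay on chromosome 19 from 5843001 to 5845000, with 15.8 RPM (14.1 to 17.6) and no IgG read, at least 8.07-fold higher than IgG. Regions on chromosome 8 (125565001 to 125567000) and chromosome 11 (75401001 to 75403000) were at least 6.95-fold and 6.79-fold higher, again without an IgG read. Those on chromosome 7 (71083001 to 71084000), chromosome 2 (167486001 to 167488000) and chromosome 8 (73314001 to 73316000) were at least 6.22-fold, 6.16-fold and 6.09-fold higher. Regions on chromosome 15 (58720001 to 58722000) and chromosome 5 (139625001 to 139627000) were at least 5.82-fold and 5.75-fold higher. A 1-kb region on chromosome 18 (32070001 to 32071000) held 211 H3KAc reads and no IgG read, at least 5.46-fold higher. The 20 regions with the highest lower bound lay on 14 chromosomes and had 9.69 to 24.5 RPM in H3KAc. For the 17 of them without an IgG read, H3KAc was at least 4.94-fold to 8.07-fold higher. Over 8 alternative settings, the lowest lower bounds of the 10 regions given here were, in the same order, 3.97, 3.77, 3.19, 3.27, 2.93, 2.78, 1.63, 2.82, 2.57 and 2.41. The 1.63 came with IgG over 11 bins, the 2.78 with thinned H3KAc and the others with reads of 1 strand, while all deposited reads raised these bounds to between 20.2 and 34.7.

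The widest region spanned 5 kb on chromosome 7, from 132695001 to 132700000. It had 38.4 RPM in H3KAc (35.7 to 41.2) and 4.22 RPM in IgG, a ratio of 9.10 (4.59 to 21.2) from 756 and 8 reads. A 4-kb region on chromosome 17 from 25150001 to 25154000 had 24.3 RPM and a ratio of 15.4 (5.23 to 74.8), with 3 IgG reads. On chromosome 6, 3-kb regions from 91064001 to 91067000 and from 31166001 to 31169000 had ratios of 15.2 (4.16 to 126) and 14.5 (3.98 to 120). Regions of 3 kb on chromosome 10 (79481001 to 79484000) and chromosome 12 (66174001 to 66177000) had ratios of 12.0 (3.28 to 99.5) and 9.96 (2.72 to 82.8). Each of these 4 rested on 2 IgG reads. The lower bound of the chromosome 12 region was 1.78 with plus-strand and 1.72 with minus-strand reads alone, and that of the chromosome 10 region 1.63 with plus-strand reads and 1.61 with IgG over 11 bins.

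Wider regions, termed domains here, were called when IgG was taken over 11 bins, an alternative chosen after seeing the data. It called 30357 bins in 22829 regions, of which 256 were 5 kb or wider and 20 were 10 kb or wider. This rule also called 18800 simulated bins without a difference. H3KAc peaks were built into both simulated libraries, so that number does not estimate the false calls here. Low regional IgG enters the calls of this rule as well as high H3KAc. In all 10 of the widest domains IgG was lower than in the 30 kb on each side, and in 9 of them H3KAc was higher. When both libraries were divided at random, bins called in the first part had a ratio of 3.70 there and of 2.79 in the second part. Averaged over all regions of this rule, IgG also peaked, at 0.879 RPM per kb within 500 bp of region centres against 0.292 RPM per kb beyond 4 kb, while H3KAc had 2.71 and 0.487 RPM per kb. The widest domain covered 27 kb of chromosome 14, from 54809001 to 54836000, with 49.6 RPM (46.6 to 52.8) in H3KAc. Its ratio to IgG over the same 27 kb was 7.85 (4.47 to 15.2). H3KAc averaged 1.84 RPM per kb inside and 1.27 in the 30 kb on each side, where single bins reached 4.87, and IgG averaged 0.234 inside and 0.369 outside. A 21-kb domain on chromosome 2 from 11557001 to 11578000 had a ratio of 13.3 (5.15 to 48.8). Its highest bin held 2.08 RPM in H3KAc, against 3.35 RPM for the highest bin in the 30 kb on each side. A 17-kb domain on chromosome 11 from 86391001 to 86408000 had a ratio of 8.09 (4.38 to 16.9), and a 15-kb domain on chromosome 15 from 66621001 to 66636000 one of 10.6 (4.82 to 28.9). A 14-kb domain on chromosome 11 from 87557001 to 87571000 had 63.7 RPM and a ratio of 4.83 (3.26 to 7.50). Here too the highest H3KAc bin lay outside, with 7.15 RPM against 6.65 RPM inside. The widest region of the first rule became a 13-kb domain, from 132694001 to 132707000 on chromosome 7, with 74.3 RPM and a ratio of 7.05 (4.55 to 11.6). In the domains given here other than those of 21 kb and 14 kb, the highest H3KAc bin lay inside.

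**Figure D3:**
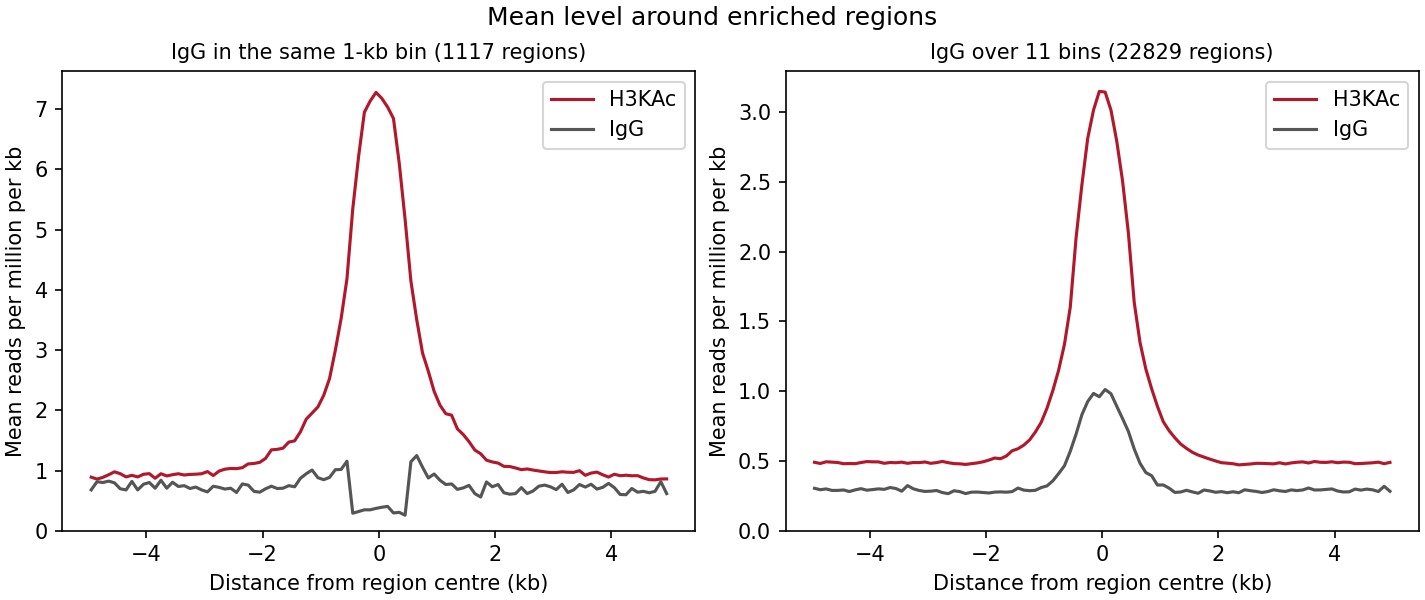
Mean level in RPM per kb (y axis) of H3KAc and IgG by distance from the centre of enriched regions in kb (x axis), for regions called with IgG in the same bin (left) and with IgG over 11 bins (right). IgG is lowest inside regions called with the same bin, where few IgG reads were required, and highest just outside them, at 1.25 RPM per kb 650 bp from the centre. It peaks with H3KAc in regions called with IgG over 11 bins.

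**Figure D4:**
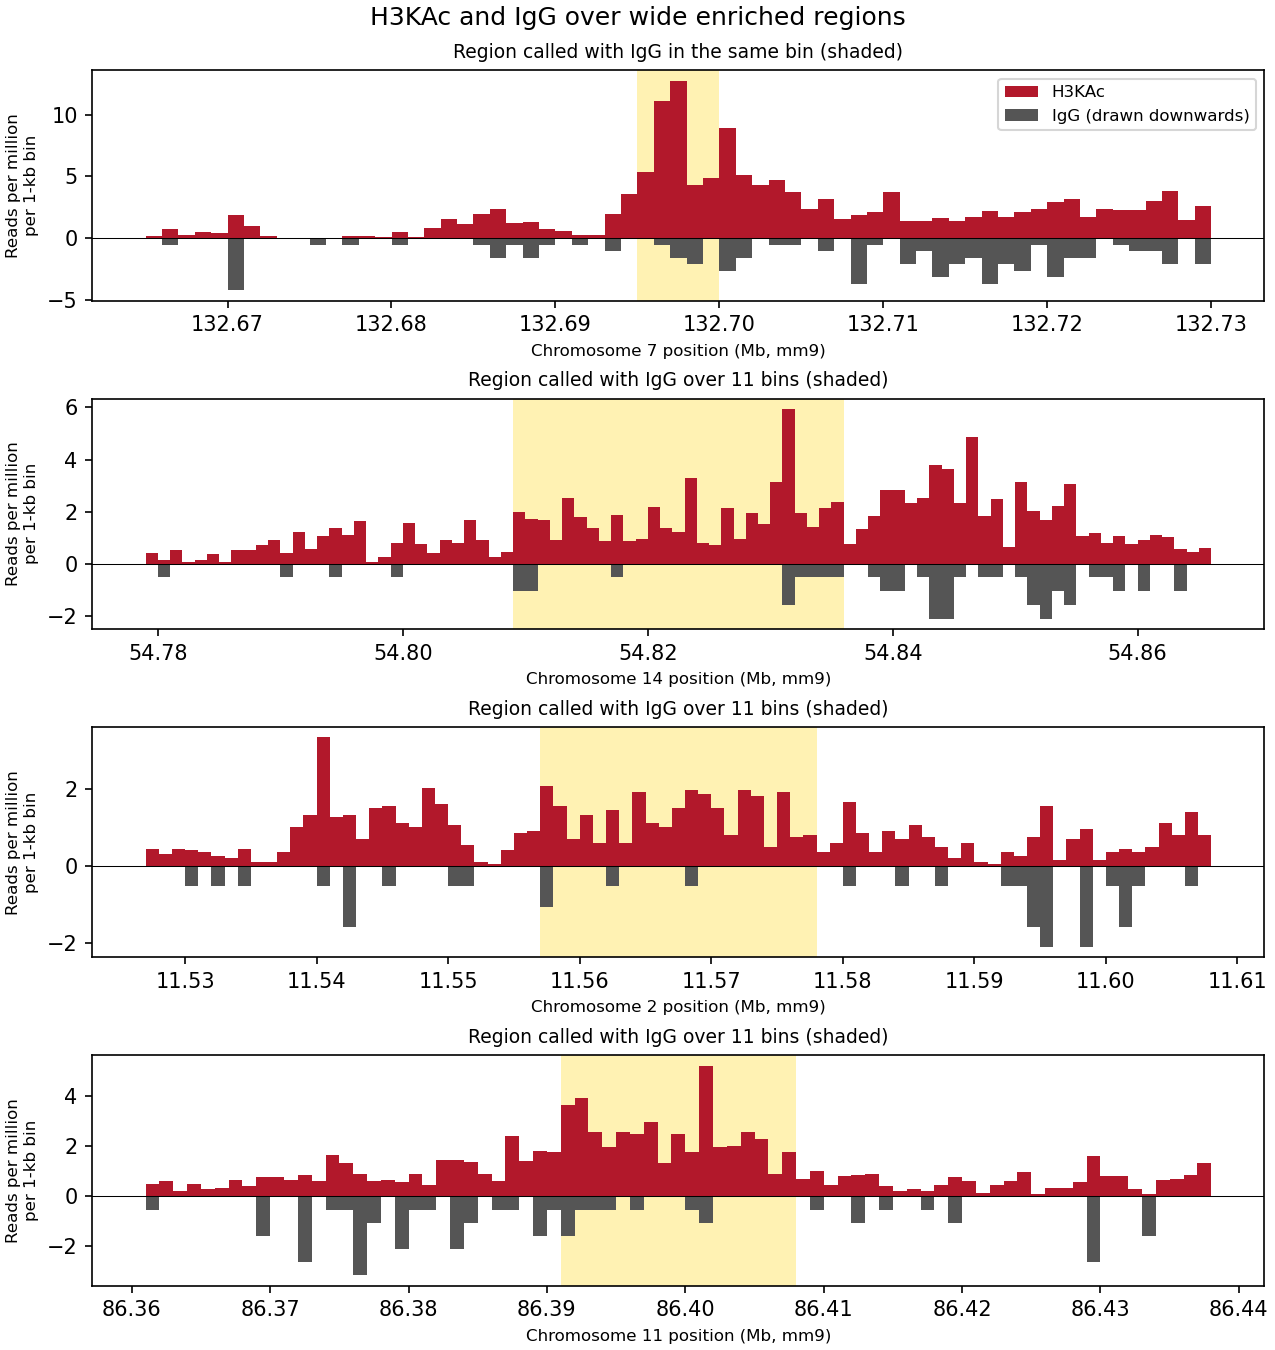
RPM in 1-kb bins (y axis, H3KAc upwards and IgG downwards) by mm9 position in Mb (x axis) over the widest region called with IgG in the same bin (top, chromosome 7) and the 3 widest called with IgG over 11 bins, with 30 kb on each side. The shaded region of 5 kb on chromosome 7 holds 756 H3KAc and 8 IgG reads, and the shaded 27 kb on chromosome 14 holds 978 and 12.

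The chromosomes differed in how many enriched regions they held. Autosomes had 0.517 regions per 1000 covered kb (exact Poisson 95% interval 0.487 to 0.548). Chromosome 11 had the highest rate of the autosomes, with 115 regions or 1.03 per 1000 kb (0.851 to 1.24), followed by chromosome 19 with 0.867 (0.637 to 1.15) and chromosome 17 with 0.797 (0.616 to 1.01). Chromosome 14 had the lowest rate of the autosomes, with 34 regions or 0.330 per 1000 kb (0.229 to 0.461). Chromosome X had 8 regions or 0.0775 per 1000 kb (0.0334 to 0.153). Depth moved with these counts, and autosomes thinned towards the depth of X had fewer enriched bins per covered kb than X (given below). Chromosome 11 had 12.1 H3KAc and 1.17 IgG reads per covered kb, the autosomes together 9.05 and 0.869, and chromosome X 3.16 and 0.335. With IgG over 11 bins, chromosome 11 had 13.1 regions per 1000 kb (12.5 to 13.8), chromosome 19 had 13.3 (12.4 to 14.3) and chromosome X had 5.35 (4.92 to 5.82), against 10.4 (10.3 to 10.5) over the autosomes.

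**Figure D5:**
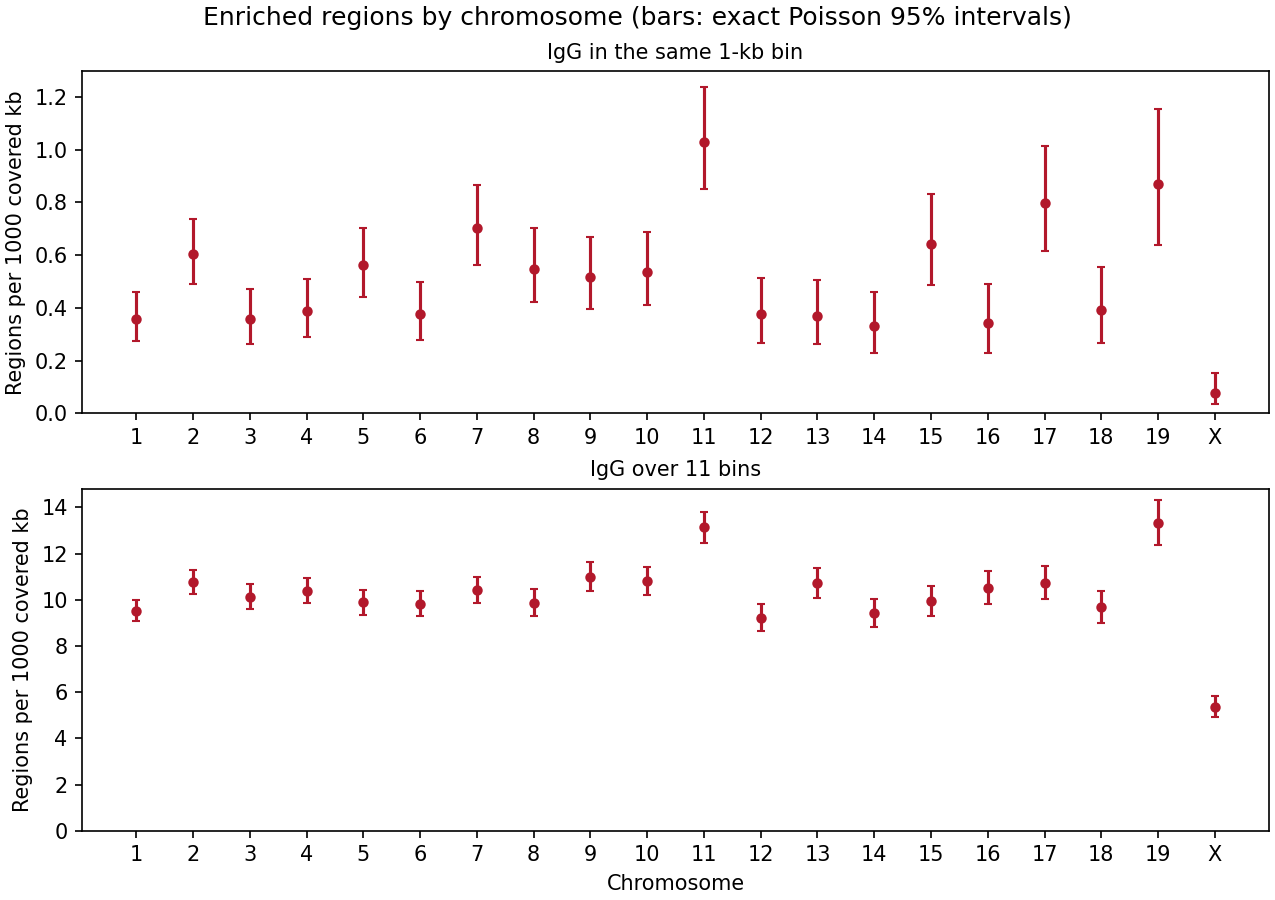
Enriched regions per 1000 covered kb (y axis) for each autosome and chromosome X (x axis), with exact Poisson 95% intervals, for regions called with IgG in the same bin (top) and over 11 bins (bottom). Chromosome X lies lowest in both, at 0.0775 and 5.35, and chromosome 11 lies above the autosomal rates of 0.517 and 10.4 in both.

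Mitochondrial DNA, which carries no histones, was also higher in H3KAc. It gave 1368 H3KAc and 35 IgG positions, a ratio of 3.76 (2.69 to 5.43), and 3.01 (2.59 to 3.52) with all deposited reads, copies counted as independent. A 3-kb mitochondrial region from 12001 to 15000 was among the 10 widest enriched regions, with a ratio of 7.55 (3.21 to 23.4) from 392 and 5 reads. Its lower bound was 1.87 with plus-strand reads alone. Of 17 covered mitochondrial bins, 3 were called with IgG in the same bin, in 2 of the 1117 regions, and 11 with IgG over 11 bins. An enriched call or a ratio of this size therefore does not by itself show acetylated histone H3.

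The bins with the most IgG reads were lower in H3KAc when distinct positions were counted, but the counting fixed this in advance. A 1-kb bin has at most 2000 positions on both strands. Out of 19711169 H3KAc positions, these are too few to reach the IgG levels in RPM of the 5 bins given here. On chromosome 17, bins starting at 39981001, 39982001, 39980001 and 39985001 had 336, 299, 255 and 187 RPM in IgG, and their ratios were 0.211, 0.221, 0.221 and 0.222. The fifth bin, on chromosome 2 from 98502001 to 98503000, had 171 RPM in IgG and a ratio of 0.187 (0.163 to 0.214). With all deposited reads, the ratio over the 3 bins of chromosome 2 among the 20 highest in IgG turned from 0.171 to 1.48, while that over 6 bins of chromosome 17 rose from 0.224 to 0.488. Genome-wide, 8866 bins were under-represented in H3KAc, and between 409 with thinned H3KAc and 96896 with all deposited reads under the alternative settings.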

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

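The test on the repeated reads was chosen after the values had been seen. Reads removed as repeats of a position were examined as data outside the main counts, and 3 bins of chromosome 2 held more of them per 1000000 reads in H3KAc than in IgG. The bin from 98507001 to 98508000 held 68691 removed H3KAc reads and 13255 removed IgG reads, a ratio of 1.81 (1.78 to 1.84). The bins from 98502001 to 98503000 and from 98503001 to 98504000 had ratios of 1.26 (1.24 to 1.29) and 4.15 (3.94 to 4.37). With distinct positions the same bins had ratios of 0.152, 0.187 and 0.280. The intervals of removed reads count copies of 1 position as independent and may be too narrow. In the bin from 98507001, the removed reads lay on 476 H3KAc and 301 IgG positions.

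A technical candidate explanation for low ratios among distinct positions in repeat bins is that a small number of positions is filled in the deeper library. It was examined on bins among the 20 highest in IgG. On chromosome 2 these were 3 bins, of which 2 are among those above, and counting every deposited read gave a ratio of 1.48 (1.461 to 1.499) in place of 0.171. Removed repeats were 98.8% of the H3KAc reads there, so this value restates the ratios above and decides nothing. For 6 neighbouring bins of chromosome 17 from 39980001 to 39986000, the ratio with every read was 0.488 (0.4768 to 0.4997), still below 1. Filled positions thus did not appear to be the whole reason there. The intervals with every read also count copies as independent and may be too narrow. Among distinct positions, the limit of 2000 per 1-kb bin alone held the ratio over either set of bins below 1. The limit was not reached in the bin from 98502001 to 98503000, where H3KAc held 628 positions. Filled positions stay open on chromosome 2 and unequal amplification of the libraries on both chromosomes, and no biological explanation was tested.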

How the results depend on the processing

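The alternatives with IgG over 11 bins, measured read shifts and 1 strand were chosen after seeing the data. The 1178 enriched bins became 39577 with all reads as deposited, 27 with a lower bound above 4, 9177 with a lower bound above 1, 638 with 500-bp bins, 30357 with IgG over 11 bins, 127 with plus-strand reads and 128 with minus-strand reads. They stayed within 1.5 times of the main count with reads not moved (1206 bins, 990 shared), IgG scaled by background bins (968, all shared), H3KAc thinned to the IgG number (954, of which 636 were shared) and measured shifts (1233, 1088 shared). The 0.517 autosomal regions per 1000 covered kb became 14.6 with all reads, 0.430 with background scaling, 0.0126 and 3.29 with lower bounds above 4 and above 1, 0.672 with thinned H3KAc (924 regions against 1117, over fewer covered kb), 0.329 with 500-bp bins, 10.4 with IgG over 11 bins, and 0.0631 and 0.0651 with plus-strand and minus-strand reads. With all reads, the 4.02 reads per IgG position entered the intervals as if independent, and 1 strand removes about as many reads as it keeps; other causes were not tested. Of the 26 regions named for their lower bound or width, which leave out the 5 bins with the most IgG reads, 25 held a called bin with reads not moved and with measured shifts, 24 with background scaling and with IgG over 11 bins, 22 with thinned H3KAc, 19 with 500-bp bins, 10 with plus-strand reads, 8 with minus-strand reads, 6 with a lower bound above 4, and 26 with all reads and with a lower bound above 1. Summed over their fixed coordinates, the lower bound fell by over 1.5 times in 24 regions with plus-strand and 19 with minus-strand reads, and in 4 each with reads not moved, thinned H3KAc and IgG over 11 bins; it rose as much in 23 with all reads and 11 with IgG over 11 bins. By the rule with IgG in the same bin, 79 H3KAc reads were the fewest in a called bin without an IgG read. Promoter, transcription start site and gene list alternatives, and the place of regions relative to genes, were not run without mm9 gene positions. No paired analysis was possible because each group has 1 library.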

Other observations

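The test of opposite-strand distances was chosen after its values had been seen; the tests by copy number and by thinning were written down before their results.

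In IgG, read starts on opposite strands were paired at a fragment's length. Of plus-strand positions, 51.4% had a minus-strand position within a 200-bp window that began 75 bp downstream, and 14.2% had one in the mirrored window upstream. The number of pairs downstream was 2.83 times that upstream, and 1.26 times in H3KAc. Equal numbers had been taken as the mark of local clustering, but fragments clustered at a site also place minus-strand starts downstream, so clustering stays open. If both ends of the same amplified fragment were read, partners should be more frequent at positions read more often: the excess was 27.7 percentage points at positions read 1 time and 42.1 points at positions read 5 or more times. The excess also rose in H3KAc, from 8.24 to 10.8 points, so a rise in this window is not specific to IgG. In H3KAc, however, the window leaves out the peak, and 58.8% of plus-strand positions had an upstream partner. As a hypothesis, distinct IgG positions may overcount molecules, and the intervals of the ratios may be too narrow; no biological explanation was tested.

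Chromosome X had few enriched bins, 0.0871 per 1000 covered kb (0.0398 to 0.165) against 0.545 on the autosomes. When autosomal reads were thinned at random to the depth of X, they gave 0.00915 enriched bins per 1000 covered kb over 20 draws (0.00665 to 0.0128). If depth alone set the count, a thinned rate inside the interval of X had been predicted, and if not, one above it; the rate fell below it, so neither was met. Thinning matched only the mean depth over the kb covered beforehand, and lower depth may still contribute to the low rate. Fewer autosomal kb stayed covered, 1803829 of 2141121 in the first draw, so their depth per covered kb stayed above that of X. With IgG over 11 bins the values were 7.02 (6.52 to 7.55) on X and 6.06 on thinned autosomes. By both rules the thinned autosomes thus had fewer enriched bins per covered kb than X, so no deficit of X remained against them. Depth, a difference in chromatin and an uneven spread of reads along X stay open as causes of the rate on X. An uneven spread and chromatin were not tested.

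The mitochondrial H3KAc reads were uneven along the genome, with 216 in the bin from 12001 to 13000, 144 in the bin from 11001 to 12000 and 38 in the bin from 7001 to 8000.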
